A study of Mus musculus with 8 samples.

How the data were processed

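RNA sequencing libraries were analysed from the skin of C57BL/6 embryos, 8 libraries in all: 2 of wild-type and 2 of labelled Cyp26b1-/- whole skin at E16.5, and at E18.5 1 control (Cyp26b1f/+) and 1 En1cre;Cyp26b1f/- library from each of dermis and epidermis. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit. The series' design text mentions duplicates, and further E18.5 libraries are not analysed here. Per the submitters' processing notes, TopHat 1.3.2, Bowtie 0.12.7.0, Cufflinks and Cuffdiff 1.3.0 were used with mouse build mm9, with no role or setting stated. Strand handling and the gene model are not given in the sources used here.

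The deposited tables hold, per the file headers, 1 row per RefSeq transcript with the FPKM of the control and of the mutant group, the log2 fold, a test statistic, a p-value, a q-value and a status. The FPKM values deposited by the authors are printed to 2 decimals, normalised for length and library size, and the E16.5 columns pool the libraries of a group. The log2 folds in the authors' deposited tables are log2(mutant/control) without a pseudocount. The test statistic, a score deposited by the authors, has the opposite sign to the fold, and its two-sided normal p differed from the authors' deposited p-value by at most 0.00401 in the E16.5 table. The SE of each log2 fold was therefore taken as the fold divided by the statistic, with a median of 0.169 at E16.5, 0.751 in dermis and 0.542 in epidermis over tested transcripts of at least 1 FPKM. This SE is that of Cuffdiff's model, not a spread between animals. Rows whose status marked a failed, too high or too low data estimate (1080, 7 and 271 transcripts at E16.5) can list 0 FPKM for abundant genes, and genes with such a row were left out of own folds. They include Col1a1, Krt1 and Krt10 at E16.5. Locus starts count from 0: of 1096 olfactory receptor genes compared with the GENCODE annotation of the same build, 807 had a start 1 below the annotated one and 6 an equal one, so 1 was added.

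FPKM were summed per gene symbol, since 3624 symbols had several transcripts. The size of a difference is log2((mutant FPKM + 1)/(control FPKM + 1)), with a pseudocount of 1, which understates the change of low genes, over genes with at least 1 FPKM in either group. As the median log2 fold differed from 0 in every table, folds are given relative to it. No count test was run, because the files hold no counts. For E16.5 the planned test was the authors' call at q < 0.05. An alternative chosen after seeing the data recomputed the deposited statistic after subtracting the median deposited log2 fold, with Benjamini-Hochberg adjustment over tested transcripts. The Results use this alternative for rose and fell. Transcripts with 0 FPKM in 1 group kept the authors' call. A gene counted as called when at least 1 transcript was called one way and none the other way. For E18.5, with 1 library per group, no p-value was computed, and genes were counted by a 2-fold difference. Gene names that differ by near-identical copies, such as the Lce1 or crystallin gamma genes, may share reads, and overlapping genes cannot be told apart without strand.

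Before the data were examined, 28 gene lists were fixed (retinoid genes, keratinocyte layers, follicle, dermal cell types, blood, muscle, cell cycle, stress and sex). For E16.5, calls in a list were set against 16263 tested genes with a one-sided Fisher's exact test for each direction, adjusted by Benjamini-Hochberg over 56 tests, and calls adjusted over the list alone used the smallest p of a gene's transcripts times their number. In every comparison, the list's median was given a percentile among 10000 random lists of the same size matched on level, and an SE from 2000 bootstrap draws of members. Lists with too few members at 1 FPKM were given no median (mucous epithelium at E18.5, and endothelial and cartilage and bone genes in the epidermis). A further 5 lists were written after the data had been seen. The genes named were set by a rule: Cyp26b1, the 10 highest and 10 lowest folds among the authors' E16.5 calls, the 10 highest and lowest in each E18.5 tissue with at least 5 FPKM in either group, and up to 4 members of each list with the largest fold in a comparison. Symbols with several transcripts, short RNAs, predicted genes and sex-linked genes were left out of the ranked names. Basal keratinocyte and fibroblast genes were also fixed for the comparison of levels between tissues. Named after their values were seen were Rarres1, Tchh, Lce3f, Lor, Krt5, Xist, Mall and Gsta4 at E16.5, Fabp4 in dermis, and the members of the 5 later lists. Some single genes that the rule would name are not reported here. Short RNA genes made up 139 of the 2-fold genes in dermis and 85 in epidermis.

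The procedure was tested on simulated data. With the E16.5 table's implied SE, a shift of 0.5 and a known set of changed transcripts, the recomputed test called 88% of transcripts changed by 1 log2 unit and 97% of those changed by 2, with 13 false calls. Without the subtraction 10976 unchanged transcripts were called. With the dermis table's SE, 1% and 13% were called. The simulated noise had the SE that the test assumes, so the false calls do not cover a spread between animals. In simulated dermis folds, drawn independently for each gene, 1 of 26 unchanged lists lay outside the middle 95% of random lists. Genes of a real list may vary together, so the simulation does not show how often such lists lie outside it without an effect of genotype. GC content came from GENCODE transcripts of the same build and was matched by symbol for 94.9% of expressed genes at E16.5. Alternatives tried were a pseudocount of 0.1, no filter, filters of 1 and 5 FPKM, thresholds of 1.5-fold and 4-fold, q < 0.01, centring on the median gene or on the median of 20 GC bins, and the authors' calls. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Read depth is unknown, so no counting error is given.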

Results

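RNA was sequenced from the skin of C57BL/6 mouse embryos at 2 ages. At embryonic day 16.5 (E16.5), whole skin labelled Cyp26b1-/- was set against wild-type skin, with 2 libraries in each group. At embryonic day 18.5 (E18.5), dermis and epidermis were sequenced separately, with 1 library labelled En1cre;Cyp26b1f/- and 1 control library for each tissue. Cyp26b1 encodes a cytochrome P450 enzyme that breaks down retinoic acid, and En1cre drives recombination in cells that have expressed Engrailed 1, which include cells of the trunk dermis. The comparisons ask which transcripts differ in embryonic skin when this enzyme is removed from the whole embryo or from En1cre-expressing cells. By the E18.5 labels, the mutant (f/-) also carries 1 Cyp26b1 allele fewer than the control (f/+) outside the En1cre-expressing cells. The E18.5 comparisons cannot separate these 2 differences. The values are fragments per kilobase of transcript, scaled to library size (FPKM), for 27641 RefSeq transcripts with 21882 gene symbols in each of 3 tables. The E16.5 columns each pool 2 libraries, so no spread between libraries could be computed, and the E18.5 comparisons had no replicates. Read depth is unknown, because FPKM values do not carry it. Replicate labels did not say whether libraries came from separate animals, so the authors' p-values describe these libraries.

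The targeted gene, summed over its transcripts, was not lower in the libraries labelled mutant, although 1 of its transcripts was at E16.5. Cyp26b1 lies on the minus strand of chromosome 6 from 84521408 to 84543902 (mm9) and has 2 listed transcripts. At E16.5 the transcript NM_001177713 went from 19.4 to 14.4 FPKM between wild-type and labelled-null skin, and NM_175475 from 15.5 to 43.8 FPKM. In the authors' deposited table the log2 folds were -0.44 (SE 0.15 implied by the test statistic, q = 0.009) and 1.5 (SE 0.14, q listed as 0). Minus the median fold of the authors' deposited table they were -0.91 and 1.02. In the dermis the same transcripts went from 48.7 to 59.7 FPKM and from 5.42 to 42 FPKM, and in the epidermis from 4.97 to 11.8 FPKM and from 0 to 1.89 FPKM. The summed log2 fold relative to the median gene was 0.29, 0.77 and 1.48 in skin, dermis and epidermis. The labels do not say which exons the alleles lack, and a table of whole transcripts cannot show whether part of a transcript is missing. The genotype was therefore neither checked nor contradicted by these values, and each direction given here rests on the labels.

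In E16.5 skin labelled null, genes that respond to retinoic acid rose, and genes of the hair shaft, the inner root sheath and the outermost epidermal layers fell, each relative to the median gene. Stra6, a membrane receptor for retinol-binding protein, rose from 1.47 to 44.8 FPKM. Stra6 is expressed in the eye as well, and lens genes rose in the same libraries, so the source of its rise stays open. Krt71, a keratin of the inner root sheath, fell from 47.9 to 0.28 FPKM, and Klk7, a protease of corneocyte shedding, from 127 to 6 FPKM. The largest rises were in crystallins, the structural proteins of the eye lens. These changes stood on a broad shift: among 14154 genes with at least 1 FPKM, the median log2 fold was 0.43 on the log2(FPKM + 1) scale, and 0.48 on the scale of the deposited folds. The authors' deposited table called 10707 of 19608 tested transcripts at q < 0.05, 9935 higher and 772 lower, so 92.8% of calls were higher. When the deposited test statistic was recomputed after subtracting the median, 1532 transcripts were higher and 1854 lower, and 45.2% of calls were higher. Folds are therefore given on the log2 scale relative to the median gene. Rose or fell refers to this recomputed test, chosen after the data were seen, with Benjamini-Hochberg adjustment at 0.05. At the 2-fold level, 236 genes were higher and 403 lower relative to the median. Log2 folds were lower for transcripts richer in GC (Spearman rho = -0.33 across genes, which are not independent replicates).

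**Figure D1:**
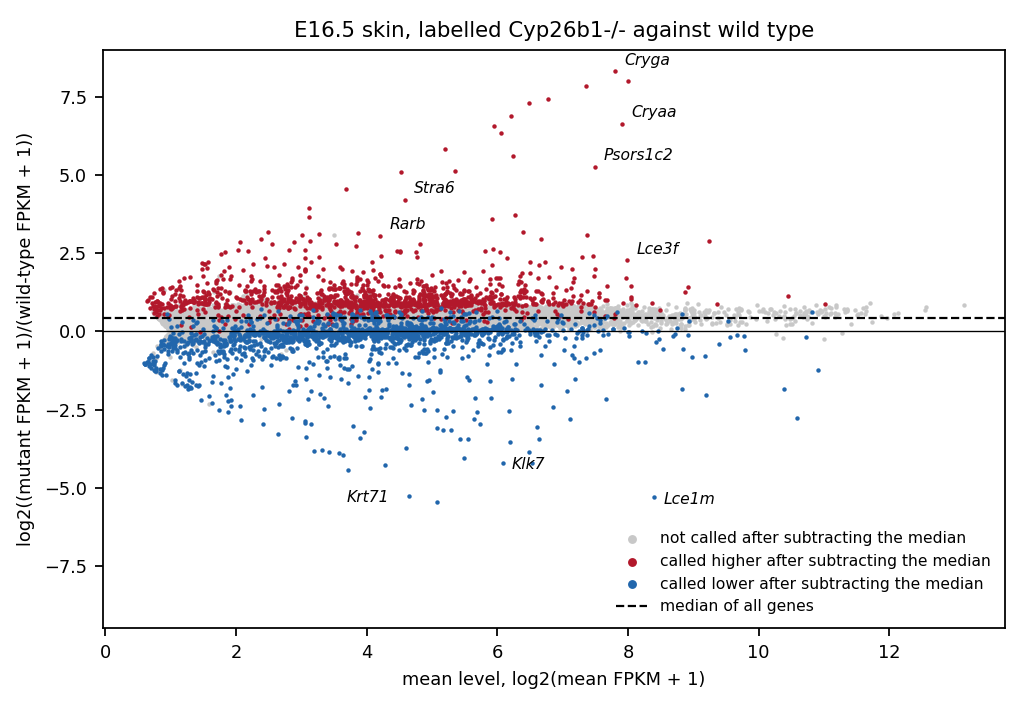
Log2 fold between labelled-null and wild-type E16.5 skin (vertical axis) against mean level, log2(mean FPKM + 1) (horizontal axis), one point per gene with at least 1 FPKM in either group, short RNA genes left out. The dashed line is the median of 0.43, and coloured points are genes called after the median deposited log2 fold of 0.48 was subtracted in the deposited statistic.

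In the retinoic acid response list, 8 rose and 2 fell of 14 tested (8 and 2 adjusted over the list alone), an enrichment among higher genes (one-sided Fisher's exact test, adjusted p = 4.9e-05 over 56 tests). The log2 fold of Stra6 was 3.78. Rarb, a retinoic acid receptor whose promoter carries a response element, rose from 2.98 to 32 FPKM (2.62). Dhrs3, which reduces retinaldehyde to retinol, rose from 44.5 to 126 FPKM (1.05), and Crabp2, a retinoic acid carrier, from 64.2 to 172 FPKM (0.98). Rarres1 fell from 26.3 to 14.3 FPKM (-1.27). The authors' deposited table called 11 higher and 1 lower, and with those calls the enrichment did not pass the threshold (Fisher's exact test, adjusted p = 0.251), where 54.7% of all tested genes were called higher. Of genes for retinoid synthesis, transport and receptors, 4 rose and 2 fell of 14 tested (4 and 3 adjusted over the list alone), with no enrichment (Fisher's exact test, adjusted p = 0.0826 for higher and 0.761 for lower genes). Crabp1, another retinoic acid carrier, rose from 171 to 355 FPKM and Aldh1a1, a retinoic acid synthesising enzyme, from 3.04 to 8.68 FPKM. In the same libraries 15 of 16 lens crystallin genes and 10 of 15 retina and pigment epithelium genes rose (lists written after the crystallin rises had been seen, so given no p-value), with the lens gene Cryaa from 3.75 to 476 FPKM and the retina gene Rax from 0.04 to 4.82 FPKM, the latter named after its values were seen.

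Of the hair matrix, shaft and inner root sheath genes, 1 rose and 22 fell of 27 tested (1 and 22 adjusted over the list alone), with the smallest adjusted p of the lists under this test (Fisher's exact test, adjusted p = 3.2e-16). The authors' deposited table called 4 higher and 21 lower. Krt71, on chromosome 15, 101564380 to 101573528 (mm9), had a log2 fold of -5.68, and its deposited log2 fold minus the median was -7.88 (SE 0.40) in the authors' deposited table. Krt25 and Krt27, other keratins of the inner root sheath, fell from 36 to 0.92 FPKM (-4.69) and from 27 to 2.04 FPKM (-3.63). The keratin-associated genes Krtap8-1 and Krtap3-2 fell from 10.3 to 0.16 FPKM and from 24.1 to 0.17 FPKM. Tchh, which encodes trichohyalin, was the member that rose, from 22.5 to 58 FPKM. Of placode and follicle signalling genes, 3 rose and 7 fell of 19 tested (3 and 8 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00923 for lower genes, list median 0.17 on the authors' scaling and -0.26 relative to the median gene). Lhx2, a follicle transcription factor, fell from 10.6 to 4.85 FPKM (-1.42), while the Wnt inhibitor Dkk4 rose from 5.06 to 14.5 FPKM (0.93) and the ligand Wnt10a from 7.66 to 16.4 FPKM (0.58). Of the Hedgehog and Wnt target genes, 0 rose and 8 fell of 13 tested (0 and 9 adjusted over the list alone; Fisher's exact test, adjusted p = 9.8e-05, list median -0.04 on the authors' scaling and -0.47 relative to the median gene), including Sp5, a Wnt target, from 2.05 to 1.36 FPKM. The authors' deposited table called 1 higher and 0 lower in this list (Fisher's exact test, adjusted p = 1 for lower genes), so its lower calls arise from the subtraction of the median. Of dermal condensate and papilla genes, 1 rose and 6 fell of 17 tested (1 and 6 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0213, list median 0.13 on the authors' scaling and -0.29 relative to the median gene), and Trps1 fell from 8.77 to 6.29 FPKM. With the calls of the authors' deposited table, 6 higher and 3 lower in the placode and follicle list and 3 higher and 3 lower in the condensate list, neither enrichment passed the threshold (Fisher's exact test, adjusted p = 0.133 and 0.12 for lower genes).

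The late cornified envelope genes, which encode proteins of the outermost epidermal layer, split by family. The 12 measured Lce1 genes fell, with log2 folds from -5.72 to -2.58, and the 4 measured Lce3 genes rose, with log2 folds from 1.16 to 2.16. Near-identical Lce1 copies may share reads, so single members are uncertain. Fisher's exact test of the list, given below, counts each copy as a separate gene, so shared reads would make its p-value too small. Lce1m fell from 660.1 to 15.8 FPKM (deposited log2 fold minus the median -5.86, SE 0.21, in the authors' deposited table), Lce1b from 174 to 8.53 FPKM and Lce1i from 84.3 to 4.1 FPKM, while Lce3f rose from 86.2 to 421 FPKM. The genes lie in the epidermal differentiation complex on chromosome 3, with the first Lce1 start at 92450454 and the first Lce3 start at 92729209 (mm9). In the list as a whole, 4 rose and 12 fell of 16 tested (4 and 12 adjusted over the list alone; Fisher's exact test, adjusted p = 3.9e-08). Of granular and cornified layer genes, 0 rose and 13 fell of 20 tested (1 and 16 adjusted over the list alone; Fisher's exact test, adjusted p = 8.2e-08). The log2 fold of Klk7 was -4.63. Klk5, another protease of corneocyte shedding, fell from 88 to 13.8 FPKM (-3.02), Cdsn, a corneodesmosome protein, from 122 to 20.2 FPKM (-2.97), and the envelope precursor Ivl from 194 to 35.7 FPKM (-2.84). Loricrin (Lor), the main cornified envelope protein, went from 2519 to 2434 FPKM and was not called. Of spinous genes, 0 rose and 6 fell of 12 tested (0 and 7 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00358, list median 0.10 on the authors' scaling and -0.33 relative to the median gene), and Calm4 fell from 2685 to 1142 FPKM. Of small proline-rich genes, 0 rose and 5 fell of 13 tested (0 and 6 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0272), and Sprr1a fell from 375 to 192 FPKM. With the calls of the authors' deposited table, 2 higher and 3 lower among spinous and 1 higher and 3 lower among small proline-rich genes, neither of these 2 lists passed the threshold (Fisher's exact test, adjusted p = 0.0567 and 0.0628 for lower genes). Basal keratinocyte genes were not enriched among lower calls, as 0 rose and 3 fell of 11 tested (0 and 7 adjusted over the list alone; Fisher's exact test, adjusted p = 0.246, list median 0.14 on the authors' scaling and -0.29 relative to the median gene, percentile 0.18 of random lists), nor were barrier lipid genes, of which 2 rose and 5 fell of 19 tested (2 and 6 adjusted over the list alone; Fisher's exact test, adjusted p = 0.115 for lower genes). Krt14 fell from 734 to 426 FPKM, and Krt5 went from 1417 to 1228 FPKM without a call.

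**Figure D2:**
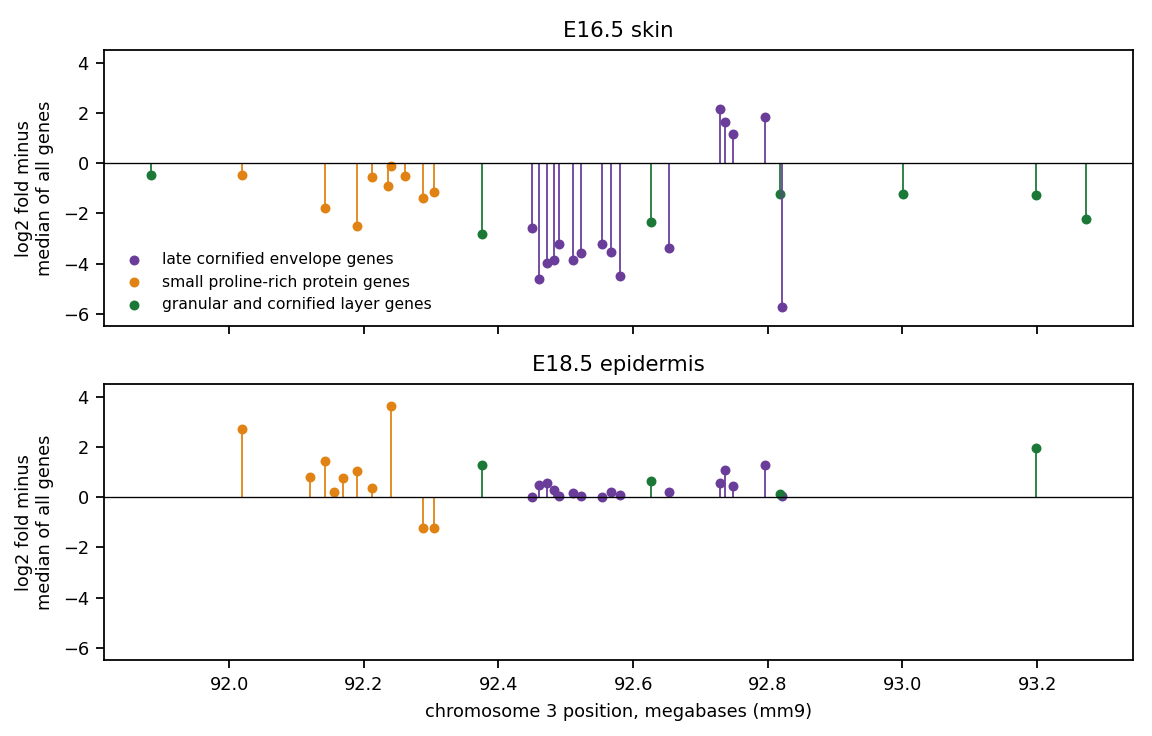
Epidermal differentiation complex on mouse chromosome 3 (mm9; horizontal axis, gene start in megabases), with the log2 fold minus the median of all genes (vertical axis) for each measured gene of 3 lists in E16.5 skin and E18.5 epidermis. In E16.5 skin the Lce1 genes lie at -5.72 to -2.58 and the Lce3 genes at 1.16 to 2.16, and in E18.5 epidermis the Lce1 genes lie at -0.01 to 0.57.

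Of keratins and other genes of periderm, simple and mucosal epithelia, 5 rose and 6 fell of 14 tested (5 and 6 adjusted over the list alone), with enrichment on both sides (Fisher's exact test, adjusted p = 0.0173 for higher and 0.00877 for lower genes). With the calls of the authors' deposited table, 7 higher and 4 lower, the lower side alone passed the threshold (Fisher's exact test, adjusted p = 1 for higher and 0.0118 for lower genes). Krt4, a mucosal keratin, rose from 55 to 295 FPKM (1.97), Upk1b, a uroplakin, from 34.6 to 130.0 FPKM (1.45), and the simple keratins Krt19 and Krt18 from 70.0 to 213 FPKM and from 20.9 to 52.2 FPKM. Of mucous epithelium genes, 3 rose and 2 fell of 11 tested (3 and 3 adjusted over the list alone; Fisher's exact test, adjusted p = 0.149 for higher genes; median of 4 members 0.64, percentile 99.92, or 86.89 with low genes kept). The mucins Muc15 and Muc20 rose from 29.1 to 98.2 FPKM and from 0.05 to 3.69 FPKM. Of epidermal alarm and inflammation genes, 3 rose and 8 fell of 19 tested (3 and 9 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00207). The interleukin 36 family gene Il1f8 fell from 49.2 to 7.86 FPKM and the defensins Defb4 and Defb14 from 7.2 to 1.39 FPKM and from 18.9 to 5.4 FPKM, and the protease inhibitor Slpi rose from 1.31 to 8.63 FPKM. The lens and retina genes that rose did so in these same libraries. Of adipocyte genes, 0 rose and 7 fell of 13 tested (1 and 9 adjusted over the list alone; Fisher's exact test, adjusted p = 0.000996), and Cfd, the adipokine adipsin, fell from 7.32 to 3.77 FPKM. The authors' deposited table called 1 higher and 1 lower in the adipocyte list, which did not pass the threshold (Fisher's exact test, adjusted p = 0.987 for lower genes).

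Of the 10 largest called rises among ranked symbols, which have 1 transcript each, 9 were crystallins: Cryga from 0.4 to 446 FPKM, Cryba1 from 0.99 to 509 FPKM, Crygb, Cryge, Crygd, Crygf, Cryaa, Crybb1 and Cryba2. The deposited log2 fold of Cryaa minus the median was 6.51 (SE 0.25) in the authors' deposited table. The other was Psors1c2, from 8.13 to 349.8 FPKM. The 10 largest falls among ranked symbols were Lce1m, Krt71, Krtap3-2, Krt25, Klk7, Lce1b, Lce1i, the histidine ammonia-lyase gene Hal from 22.5 to 0.51 FPKM, Saa1, a serum amyloid, from 21.4 to 0.52 FPKM, and Nccrp1 from 166 to 10.6 FPKM.

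Sex-linked genes differed between the pooled E16.5 groups: 4 rose and 1 fell of 5 tested (4 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0016 for higher genes). With the calls of the authors' deposited table, 4 higher and 0 lower, there was no enrichment (Fisher's exact test, adjusted p = 0.939 for higher genes). The Y-linked genes Kdm5d and Eif2s3y rose from 3.62 to 11.2 FPKM and from 21.5 to 57.8 FPKM, and Xist, expressed from the inactive X chromosome, went from 8.12 to 7.77 FPKM. Of cell cycle genes, 0 rose and 0 fell of 23 tested (0 and 0 adjusted over the list alone), where the authors' deposited table called 19 higher and 0 lower (Fisher's exact test, adjusted p = 0.0468). Apart from the adipocyte list above, calls among markers of other cells were not enriched in either direction. Of dermal fibroblast matrix genes 1 rose and 2 fell of 17 tested (1 and 2 adjusted over the list alone), of skeletal muscle genes 0 rose and 4 fell of 21 tested (0 and 3 adjusted over the list alone), and of melanocyte genes 0 rose and 2 fell of 10 tested (1 and 3 adjusted over the list alone). Of Schwann cell and nerve genes 0 rose and 1 fell of 12 tested (0 and 0 adjusted over the list alone), of endothelial genes 0 rose and 0 fell of 12 tested (0 and 0 adjusted over the list alone), and of macrophage, mast cell and other immune genes 0 rose and 2 fell of 15 tested (0 and 3 adjusted over the list alone). Of erythroid genes 2 rose and 0 fell of 11 tested (3 and 0 adjusted over the list alone), and of cartilage and bone genes 3 rose and 2 fell of 15 tested (3 and 2 adjusted over the list alone). Of immediate-early and heat shock genes 0 rose and 4 fell of 14 tested (0 and 5 adjusted over the list alone), and of Hox genes 6 rose and 1 fell of 30 tested (6 and 2 adjusted over the list alone), the lowest adjusted p of these lists being 0.107 (Fisher's exact test). By their medians relative to the median gene, erythroid genes lay above the middle 95% of random lists (0.38, percentile 99.97), and fibroblast matrix genes (-0.17, percentile 0.1) and immediate-early and heat shock genes (-0.22, percentile 0.35) lay below it. Relative to genes of like GC content, melanocyte genes (percentile 0.75) and immune genes (percentile 1.85) lay below it as well. With genes of at least 5 FPKM alone, muscle genes (percentile 1.05) and melanocyte genes (percentile 2.07) lay below it and Hox genes above it (percentile 99.66). Among single members, Bglap, which encodes osteocalcin, rose from 8.3 to 111 FPKM, Hoxc5 from 2.87 to 10.8 FPKM and Hoxc4 from 6.39 to 20.2 FPKM.

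In the E18.5 dermis labelled mutant, genes of the hair shaft and inner root sheath were lower, with a median log2 fold of -3.83 relative to the median gene. Genes of the epidermal layers and of fat cells were lower too, and genes of muscle, fibroblast matrix, vessels and immune cells were higher. Krt71, the inner root sheath keratin, went from 504 to 8.37 FPKM, Cfd from 61.9 to 0.66 FPKM, and Mylpf, a fast muscle myosin light chain, from 83.5 to 1108 FPKM. With 1 library per group these are differences between 2 libraries, with no test of genotype. Of 13398 genes with at least 1 FPKM, 2294 were at least 2-fold higher and 1509 at least 2-fold lower. The median gene was at 0.12, and after subtracting it the counts were 1871 and 1856, so the share of higher genes went from 60.3% to 50.2%. The authors' deposited table, which compares the 2 libraries, called 427 transcripts higher and 318 lower. Genes named for the dermis that were not among those calls include Krt14, Krt5, Krt17, Sparc, Crabp2 and Tgm2. The folds depended on the GC content of the transcripts (Spearman rho = -0.27 across genes, which are not independent replicates), with a median of -0.69 relative to all genes among the 20% of genes richest in GC.

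Hair matrix, shaft and inner root sheath genes lay at percentile 0 among 10000 random lists matched on level (median -3.83, bootstrap SE 0.47), and 24 of 25 measured members were at least 2-fold lower. The log2 fold of Krt71 relative to the median gene was -5.87, Krt25 went from 443 to 7.88 FPKM (-5.77), Krt35, a hair shaft keratin, from 171 to 2.48 FPKM (-5.75), and Tchh from 272 to 3.17 FPKM (-6.15). Krt27, Krt73 and Krt83 went from 255 to 5.32 FPKM, 145 to 4.87 FPKM and 34.1 to 0.51 FPKM. Follicle signalling genes were lower (median -1.70, bootstrap SE 0.26, 18 members, percentile 0), with Shh from 64.4 to 14.4 FPKM, the follicle transcription factor Sox21 from 71.2 to 7.34 FPKM and the stem cell receptor Lgr6 from 55.6 to 10.8 FPKM. Hedgehog and Wnt targets (median -0.61, bootstrap SE 0.25, 13 members, percentile 6.76) and condensate and papilla genes (median -0.15, bootstrap SE 0.52, 15 members, percentile 29.86) lay within the middle 95% of random lists, but relative to genes of like GC content the Hedgehog and Wnt list lay below it (median -0.79, percentile 0.21). Within them Ptch1, the Hedgehog receptor and target, went from 118 to 23.4 FPKM and Notum from 28.7 to 8.93 FPKM.

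Genes of the basal, spinous, granular and late cornified envelope lists were also lower in the dermis labelled mutant, and the source of these transcripts in that library was not tested. The medians were -1.15 for basal (percentile 0.05), -1.42 for spinous (percentile 0), -1.76 for granular and cornified (percentile 0), -1.87 for late cornified envelope (percentile 0) and -1.49 for periderm and simple or mucosal keratin genes (percentile 0). Krt14 went from 4276 to 1115 FPKM and Krt5 from 6265 to 1806 FPKM. Krt17 went from 3459 to 860.1 FPKM and Lce1m from 134 to 37.5 FPKM. Sprr1a, a cornified envelope precursor, went from 206 to 1.09 FPKM (-6.75). Adipocyte genes were lower (median -2.07, bootstrap SE 1.00, 13 members, percentile 0), with Plin1, the lipid droplet coat protein, from 95.7 to 5.28 FPKM, Adipoq from 59.5 to 3.5 FPKM and Cidec from 24.8 to 1.09 FPKM, while Fabp4 went the other way, from 73.2 to 317 FPKM. Immediate-early and heat shock genes were lower (median -1.19, bootstrap SE 0.61, 13 members, percentile 0.04), among them Egr3 from 159 to 20.6 FPKM and Hspa1b from 86.4 to 16.6 FPKM. Relative to genes of like GC content the median of that list was -0.65.

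The lists above the middle 95% of random lists in the dermis numbered 9, against 9 below it. Retinoic acid response genes were among the higher ones (median 0.96, bootstrap SE 0.48, 10 members, percentile 99.88; 0.32 on the authors' scaling with low genes kept, percentile 96.22, within the middle 95%), with Rarres2 (chemerin) from 16.5 to 143 FPKM, Crabp2 from 6.84 to 33.6 FPKM, Tgm2 from 11.7 to 40.3 FPKM and Stra6 from 0.46 to 2.75 FPKM. Crabp1 went from 35 to 432 FPKM (3.47), in a list of retinoid synthesis, transport and receptor genes whose median was -0.66 (percentile 4.86). The fibroblast matrix, endothelial and immune lists, given next, had medians of like size to the retinoic acid response list (0.94, 1.11 and 1.07). Whether a smaller share of epithelium in that library accounts for the higher retinoic acid response genes was not tested. Skeletal muscle genes were higher (median 1.48, bootstrap SE 0.27, 20 members, percentile 100), with Myl1 from 25 to 384 FPKM and Tnnt3 from 91.7 to 680 FPKM. Fibroblast matrix genes were higher (median 0.94, bootstrap SE 0.27, 18 members, percentile 99.83), with Dpt (dermatopontin) from 48.6 to 414 FPKM, Dcn (decorin) from 53.8 to 358 FPKM and Sparc from 683 to 4267 FPKM. Endothelial (median 1.11, bootstrap SE 0.30, 12 members, percentile 99.96) and immune genes (median 1.07, bootstrap SE 0.42, 16 members, percentile 100) were higher, with the lymphatic receptor Lyve1 from 4.17 to 49.5 FPKM, Pecam1 from 10.3 to 82.2 FPKM, mast cell chymase Cma1 from 130.3 to 1072 FPKM and Lyz2 from 6.12 to 43.3 FPKM. Erythroid, Schwann cell and nerve, and cell cycle genes had medians of 1.41, 0.74 and 0.59 (percentiles 99.35, 98.79 and 99.73), and relative to genes of like GC content the cell cycle median was 0.29 (percentile 94.53, within the middle 95%). With low genes kept the erythroid list lay within it (percentile 68.4), and with genes of at least 5 FPKM alone the Schwann cell and nerve list did (percentile 88.51). Other genes with the largest positive folds were the muscle genes Sln, Mybpc1, Itgb1bp2 and Casq1, with Ctsk, an osteoclast protease, from 6.91 to 124 FPKM, Zfp488 from 1.7 to 36.3 FPKM, the pseudogene Olfr856-ps1 and AI506816. The remaining large negative fold was that of the pseudogene Pisd-ps1, from 30.3 to 0.06 FPKM. Medians within the middle 95% were small proline-rich protein genes -0.84 (percentile 4.52), barrier lipid genes -0.49 (percentile 2.72), melanocyte genes -0.27 (percentile 19.72), cartilage and bone genes -0.43 (percentile 6.29), epidermal alarm and inflammation genes -0.20 (percentile 31.01) and Hox genes -0.26 (percentile 5.69). Of these, the small proline-rich, melanocyte and Hox lists lay below it relative to genes of like GC content (percentiles 0.48, 1.63 and 0.46), and the barrier lipid list did with a pseudocount of 0.1 (percentile 1.42). The library labelled mutant listed Xist at 0.03 FPKM against 9.63 in the control, and Eif2s3y at 2.59 against 0, so genes that mark embryo sex differ between the dermis libraries together with genotype. The sex-linked list had a median of 1.23 (percentile 99.91) over 4 members.

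**Figure D3:**
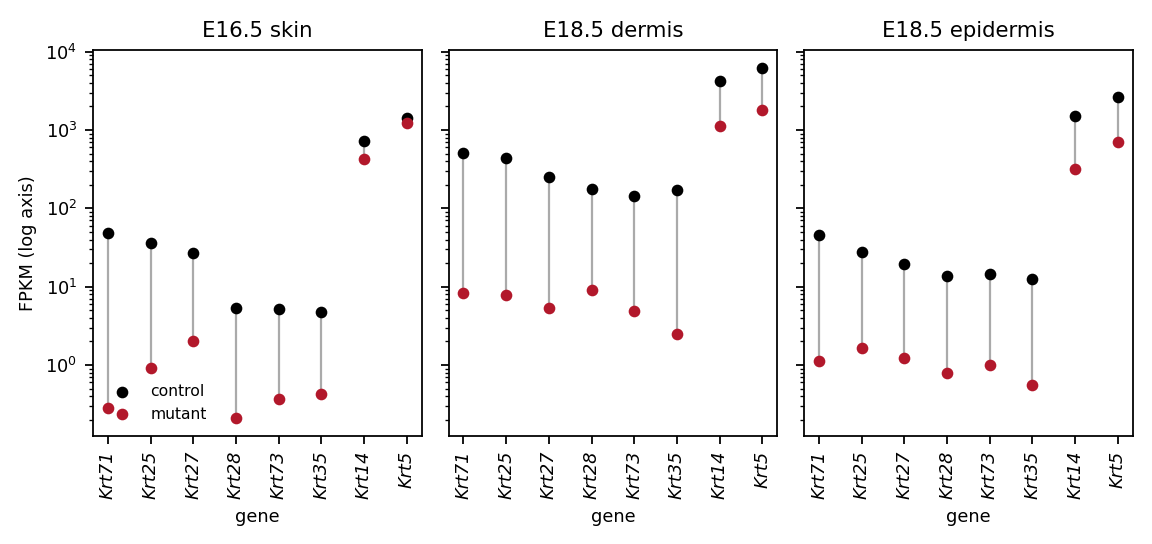
Deposited FPKM (logarithmic vertical axis) of inner root sheath and hair keratins and of the basal keratins Krt14 and Krt5 (horizontal axis) in the 3 comparisons, black for control and red for mutant, 1 value per group. Krt71 goes from 47.9 to 0.28 FPKM in E16.5 skin, from 504 to 8.37 FPKM in E18.5 dermis and from 45.3 to 1.11 FPKM in E18.5 epidermis.

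In the E18.5 epidermis labelled mutant, genes of the hair follicle, of basal keratinocytes and of fibroblast matrix were lower. Genes of the cornified layer and of the lipid barrier were higher, again between single libraries. Krt71 went from 45.3 to 1.11 FPKM, Krt14, a keratin of basal keratinocytes, from 1496 to 322 FPKM, and Tgm1, the enzyme that crosslinks the cornified envelope, from 178 to 398 FPKM. Of 11362 genes with at least 1 FPKM, 260 were at least 2-fold higher and 915 at least 2-fold lower. The median gene was at -0.18, and after subtracting it the counts were 396 and 552, so the share of higher genes went from 22.1% to 41.8%. The authors' deposited table, which compares the 2 libraries, called 194 transcripts higher and 568 lower. Genes named for the epidermis that were not among those calls include Krt5, Ivl, Tgm1, Nipal4, Aloxe3, Cyp2s1 and Crabp2. In 10 classes of level, the median log2 fold of the authors' deposited table ran from -1.18 to 0.07, so low genes are compared here with random lists matched on level.

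Hair matrix, shaft and inner root sheath genes had a median of -0.91 (percentile 0), and 9 of 21 were at least 2-fold lower. With genes of at least 5 FPKM alone, the median on the authors' scaling was -2.95. The log2 fold of Krt71 was -4.28, Krt25 went from 27.8 to 1.64 FPKM (-3.27), Krt27 from 19.7 to 1.23 FPKM and Krt35 from 12.6 to 0.55 FPKM. Follicle signalling genes were lower (median -1.09, bootstrap SE 0.17, 15 members, percentile 0), with Foxi3, a follicle transcription factor, from 12.9 to 1.59 FPKM, Lhx2 from 8.25 to 1.05 FPKM and Shh from 3.79 to 0.49 FPKM. Hedgehog and Wnt targets were lower (median -0.92, bootstrap SE 0.22, 10 members, percentile 0), with Ptch1 from 14.2 to 1.84 FPKM and Lef1 from 9.03 to 2.5 FPKM. Basal keratinocyte genes were lower (median -1.14, bootstrap SE 0.18, 12 members, percentile 0), with Krt5 from 2634 to 704 FPKM and Itga6, a hemidesmosome integrin, from 3.78 to 0.37 FPKM. At the 1 FPKM filter the hair list was therefore not lower than the basal list. How much basal layer and dermis each epidermis library held was not tested. Cell cycle genes were lower (median -0.58, bootstrap SE 0.08, 22 members, percentile 0.02), including Pcna from 47.2 to 19.6 FPKM. Periderm and simple or mucosal keratin genes were lower (median -0.48, bootstrap SE 0.46, 10 members, percentile 0.35; percentile 4.96 with low genes kept, within the middle 95%), including Krt6a from 147 to 33.7 FPKM, as were epidermal alarm genes (median -0.63, bootstrap SE 0.46, 8 members, percentile 0.02; -0.22 relative to genes of like GC content, percentile 2.82, within the middle 95%), including Krt16 from 199 to 40.4 FPKM.

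Granular and cornified layer genes were higher in the epidermis labelled mutant (median 0.66, bootstrap SE 0.15, 15 members, percentile 99.95), with Ivl from 334 to 709 FPKM and Rptn from 4.56 to 17.9 FPKM. Lor, Asprv1, Flg2 and Hrnr were left out of that list because their data were too high for an estimate. The spinous list lacked Krt1, Krt10 and Sbsn here for the same reason. Small proline-rich genes were higher (median 0.79, bootstrap SE 0.46, 10 members, percentile 99.98), with Sprr1b from 14.9 to 175 FPKM and Sprr2a2 from 19.6 to 118 FPKM, although Sprr1a went from 101 to 37.3 FPKM. Barrier lipid genes were higher (median 0.75, bootstrap SE 0.18, 19 members, percentile 100), with Nipal4 from 28.6 to 72.4 FPKM, the lipoxygenase Aloxe3 from 168 to 376 FPKM and Elovl1 from 563 to 1228 FPKM. Retinoic acid response genes were higher (median 0.82, bootstrap SE 0.40, 7 members, percentile 99.91; 0.05 on the authors' scaling with low genes kept), with Cyp2s1 from 52.2 to 103 FPKM and Crabp2 from 142 to 234 FPKM. Immediate-early and heat shock genes (median 0.51, bootstrap SE 0.17, 13 members, percentile 98.76) and Hox genes (median 0.41, bootstrap SE 0.09, 22 members, percentile 100) were above the middle 95% of random lists, the former not relative to genes of like GC content (percentile 96.16), and the Hox median was 0 on the authors' scaling with low genes kept. Late cornified envelope genes, which split by family at E16.5, had a median of 0.20 here (percentile 80.75). Lists of dermal, muscle, fat and immune cells were lower: fibroblast matrix genes had a median of -1.55 (percentile 0) with Col1a1 from 149 to 27.7 FPKM, muscle genes -0.83 (percentile 0), immune genes -0.88 (percentile 0), adipocyte genes -0.72 (percentile 0.59; 0.28 on the authors' scaling with genes of at least 5 FPKM alone, percentile 86.31) and condensate and papilla genes -1.03 (percentile 0.1). Among genes named by size, the lowest folds belonged to Krt71 and its relatives and to the class II major histocompatibility genes H2-Ab1 from 51.5 to 0.07 FPKM, H2-Aa from 38.9 to 0.14 FPKM and H2-Eb1 from 10.4 to 0.03 FPKM, with the pseudogene H2-Ea-ps listed at 0 in the library labelled mutant. Krt28 was also among them, and Grm4, a glutamate receptor, went from 14.5 to 0.71 FPKM. The highest were Sprr1b, the serine protease Prss22 from 19.4 to 105 FPKM, H2-T9, Pla2g4e from 5.45 to 29 FPKM, Catsperg1, Cyp2b19, a keratinocyte arachidonic acid epoxygenase, from 53.4 to 250.5 FPKM, Dbil5, AA465934 and Ankrd24. Ndufs5, a mitochondrial complex I subunit, was listed at 0 in the control and 7.36 FPKM in the mutant, and a 0 for such a gene may be a failed estimate. Xist was at 10.03 FPKM in the control and 0.02 in the mutant library, so genes that mark embryo sex differ with genotype here too (sex-linked list median 1.66, percentile 99.98). Medians within the middle 95% were retinoid synthesis, transport and receptors 0.25 (percentile 82.39), spinous layer genes 0.24 (percentile 59.27), melanocyte genes -0.40 (percentile 9.03), Schwann cell and nerve genes -0.20 (percentile 33.68) and erythroid genes 0.15 (percentile 75.64).

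**Figure D4:**
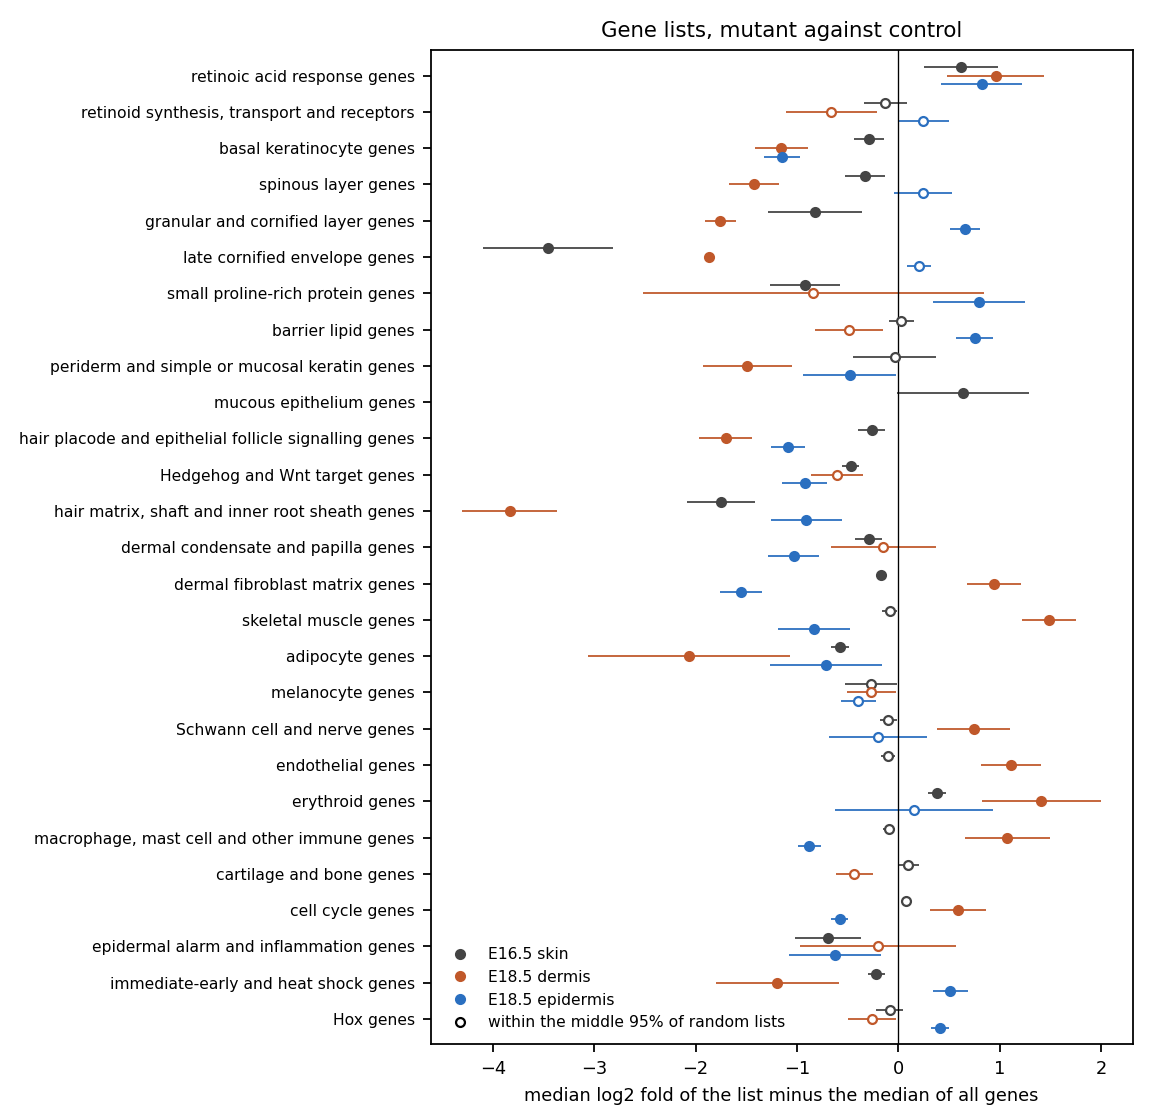
Median log2 fold of each gene list minus the median of all genes (horizontal axis) in E16.5 skin, E18.5 dermis and E18.5 epidermis, with bars of 1 bootstrap SE over members, and open points for lists within the middle 95% of 10000 level-matched random lists. Hair genes lie at -1.75, -3.83 and -0.91, and retinoic acid response genes at 0.62, 0.96 and 0.82.

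Genes lower in 1 comparison were also lower in the others more often than independent lists would be, on either scaling. Some overlaps in the opposite direction were in excess too, and no overlap was given a p-value. Log2 folds were lower for GC-rich transcripts in skin and in dermis, but not in epidermis (Spearman rho -0.33, -0.27 and 0.22 across genes). The expected numbers are those of independent lists, not matched on GC content or level, so they do not allow for such trends. The Y-linked gene Eif2s3y was higher in the mutant column of all 3 tables (21.5 to 57.8, 0 to 2.59 and 0.13 to 4.62 FPKM). Xist went from 9.63 to 0.03 FPKM in dermis and from 10.03 to 0.02 FPKM in epidermis. Changes shared by these tissues therefore cannot be told apart from a shared difference in embryo sex. At E16.5 both columns listed Xist, at similar FPKM as given above, and Y-linked transcripts, so a sex difference there was partial. Its part in the changes shared with E18.5 was not tested, nor was a shared difference in the amount of epithelium. Relative to the median in each table, 359 of 1349 genes called lower at E16.5 were at least 2-fold lower in the dermis, where independent lists would share 182 (1349 × 1720 over 12748 genes). Of genes called higher, 113 of 933 were at least 2-fold higher in the dermis, against 131. With the epidermis, 128 lower genes were shared against 55.9, and 65 higher genes against 28.7. On the authors' scaling the numbers were 171 against 41.1 lower and 1415 against 1344 higher for dermis, and 73 against 28.5 lower and 87 against 153 higher for epidermis. Dermis and epidermis shared 221 lower genes against 104 and 38 higher genes against 30.3 on that scaling, and 183 against 77.4 and 48 against 39 relative to the median. In the opposite direction, 118 genes lower in skin were higher in the dermis against 189 relative to the median, and 28 against 64.6 on the authors' scaling. Genes lower in skin and higher in the epidermis numbered 75 against 38.9, and 25 against 7.79. Genes higher in skin and lower in the dermis numbered 155 against 126, and 603 against 856. For the epidermis they numbered 35 against 41.2, and 382 against 559. Across all genes Pearson r was 0.13 between skin and dermis, -0.01 between skin and epidermis and 0.09 between dermis and epidermis (Spearman rho 0.12, -0.01 and 0.04), across genes, which are not independent replicates. Called at E16.5 and at least 2-fold in all 3 tables relative to the median were 36 lower and 2 higher genes of 10528. The lower ones included 9 genes of the hair list, and the higher ones were Mall, from 49.6 to 169.9 FPKM in skin, and Gsta4, a glutathione transferase, from 35.8 to 161 FPKM, both named after their values were seen.

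Markers of each E18.5 tissue were present in the libraries of the other. The 2 tables were normalised separately, so levels are set side by side without a test. The basal keratin Krt5 was at 6265 FPKM in control dermis and 2634 in control epidermis, and at 1806 and 704 in the mutant libraries. The matrix gene Dcn was at 53.8 in control dermis and 5.34 in control epidermis, and at 358 and 1.78 in the mutant libraries. Values for Col1a1 in the dermis cannot be used, because the estimate failed at its high level. In the opposite direction between tissues, 139 of 10838 genes were at least 2-fold higher in the dermis labelled mutant and at least 2-fold lower in the epidermis, where independent lists would share 134, and 42 were the reverse, against 23.4. Relative to the median the numbers were 79 against 66 and 86 against 45.8. These differences between tissues were not tested, since each rests on 1 library per group.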

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

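The tests in this part were chosen after the results were seen, except the GC test of the hair genes and the test of retina genes. Several lists and genes differed in opposite directions between the E18.5 tissues, by at least 1 log2 unit in each on the authors' scaling. The difference was not tested, as there was 1 library per group. Markers of each tissue were present in the libraries of the other. Col1a1 went from 149 to 27.7 FPKM in epidermis. Krt5 went from 6265 to 1806 FPKM in dermis, though it was lower in epidermis too, from 2634 to 704 FPKM. A difference in how cleanly the 2 tissues were separated was not told apart from opposite effects of genotype. Dermal fibroblast matrix genes had a median of 1.07 in dermis and -1.73 in epidermis. Skeletal muscle genes had a median of 1.60 in dermis and -1.01 in epidermis. Macrophage, mast cell and other immune genes had a median of 1.20 in dermis and -1.06 in epidermis. Among named genes, Cma1 was at 3.03 in dermis and -1.79 in epidermis, Dcn was at 2.71 in dermis and -1.19 in epidermis, Dpt was at 3.06 in dermis and -1.63 in epidermis, Fabp4 was at 2.10 in dermis and -1.44 in epidermis, Ivl was at -1.31 in dermis and 1.08 in epidermis, Myl1 was at 3.89 in dermis and -1.48 in epidermis, Olfr856-ps1 was at 4.11 in dermis and -1.54 in epidermis, Sparc was at 2.64 in dermis and -2.12 in epidermis, Tgm1 was at -1.25 in dermis and 1.15 in epidermis, Tnnt3 was at 2.88 in dermis and -1.61 in epidermis, Tyrobp was at 2.24 in dermis and -1.99 in epidermis, Zfp488 was at 3.79 in dermis and -1.06 in epidermis.

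One pattern is the excess of higher calls at E16.5. The tables argue against a bias by GC content as its whole cause, because the lowest median log2 fold among 5 classes of GC was 0.27, above 0. A scaling difference between the 2 columns predicts the same shift at every level, and the medians of the deposited log2 folds in 10 classes of level spanned 0.11, from 0.41 to 0.52 in the authors' deposited table. The same test, run first on the log2(FPKM + 1) scale, where the pseudocount shrinks the folds of low genes, gave a span of 0.26, and the FPKM of tested transcripts summed to 1.4 times the wild-type sum in the labelled-null column. A uniform rise of mRNA cancels in values scaled to library size, so FPKM hold no test of one, and the median of 0.43 says nothing for or against it without a spike-in.

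Another is the low level of hair genes in the E18.5 dermis labelled mutant. Less epithelium in that library, lost evenly, would lower keratinocyte and hair genes alike. The hair list lay -2.68 log2 units from the basal keratinocyte list (95% bootstrap interval -3.37 to -1.38, over list members and not libraries). That argues against an even loss as the whole cause in these 2 libraries. A larger loss of follicle epithelium than of other epithelium was not tested, and a part of the fall stays open because basal genes were lower too. GC content is argued against by the list's median of -3.42 after subtracting the median of each gene's GC bin. Embryo sex cannot be told apart from genotype, since Xist differed by -3.37 between the same 2 libraries. A biological difference that goes with the genotype label stays open and was not tested.

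A further one is the rise of lens crystallin genes in E16.5 skin labelled null, where Cryba1, the most abundant of them, reached 509 FPKM. Lens tissue in at least 1 of the 2 pooled samples is a candidate source: lens fibre genes other than crystallins had a median log2 fold of 2.20 on the authors' scaling, with Lim2 from 0.04 to 23.7 FPKM and Mip from 0.28 to 15.1 FPKM. Retina and pigment epithelium genes, a list written after the crystallin values had been seen and before its own were, lay at percentile 100 of random lists. Of the 3 lists of 16, 14 and 20 genes, 15, 9 and 12 were measured, but 4, 3 and 3 were at 1 FPKM or more in wild-type skin. Most members thus passed the filter only through the labelled-null column, which favours a high median and percentile, so these carry little weight. Of the retina genes, 1 stands in the melanocyte list. Stra6 and Aldh1a1 are expressed in the eye as well, so the share of their E16.5 rise that eye tissue could bring stays open. An activation of lens genes within skin was not tested, and the pooled column cannot show whether both labelled-null libraries carry the signal.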

How the results depend on the processing

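The added alternatives (subtracting the median from the E16.5 test, GC bins, the median-subtracted list calls and shared genes, the backgrounds limited by FPKM, short RNA genes left out, and every alternative for opposite effects in dermis and epidermis) were chosen after seeing the data. No paired analysis was possible because the E16.5 columns pool the libraries of a group and the E18.5 groups hold 1 library each. For the same reason a replicate block, leaving out a replicate, DESeq2 and splits of the samples could not be run. Depth is unknown, so what it limits cannot be given.

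Of the alternative values for counts and for Cyp26b1, 81 stayed within 1.5 times the reported value, or within the error for Cyp26b1, and 48 did not. Each of those follows the reported value, and their cause was not tested beyond what the setting itself fixes. For E16.5 skin, transcripts higher, 9935 became 758 at 2-fold, 1532 after the median was subtracted and 1446 after the GC-bin median was subtracted. For E16.5 skin, transcripts lower, 772 became 217 at 2-fold, 1854 after the median was subtracted and 1638 after the GC-bin median was subtracted. For E18.5 dermis, genes higher, 2294 became 4158 at 1.5-fold, 426 at 4-fold, 391 by the calls in the authors' deposited table and 1354 centred on the GC bin. For E18.5 dermis, genes lower, 1509 became 2986 at 1.5-fold, 241 at 4-fold and 286 by the calls in the authors' deposited table. For E18.5 epidermis, genes higher, 260 became 807 at 1.5-fold, 60 at 4-fold, 396 centred on the median gene and 158 by the calls in the authors' deposited table. For E18.5 epidermis, genes lower, 915 became 1868 with pseudocount 0.1, 523 at 5 FPKM, 2507 at 1.5-fold, 101 at 4-fold, 552 centred on the median gene, 525 by the calls in the authors' deposited table and 504 centred on the GC bin. For E16.5 lists enriched among transcripts called higher, 1 became 0 with a background of 1 FPKM, 0 with a background of 5 FPKM and 3 after the median was subtracted. For E16.5 lists enriched among transcripts called lower, 5 became 11 after the median was subtracted. For higher genes shared by skin and dermis, 1415 became 2568 at 1.5-fold and 113 with the median subtracted from calls and folds. For lower genes shared by skin and dermis, 171 became 104 at 5 FPKM and 359 with the median subtracted from calls and folds. For higher genes shared by skin and epidermis, 87 became 151 centred on the median gene and 344 at 1.5-fold. For lower genes shared by skin and epidermis, 73 became 43 at 5 FPKM, 112 at 1.5-fold and 128 with the median subtracted from calls and folds. For higher genes shared by dermis and epidermis, 38 became 61 with pseudocount 0.1 and 164 at 1.5-fold. For lower genes shared by dermis and epidermis, 221 became 429 with pseudocount 0.1, 129 at 5 FPKM and 748 at 1.5-fold. For genes higher in dermis, lower in epidermis, 139 became 300 with pseudocount 0.1, 69 at 5 FPKM, 79 centred on the median gene and 78 centred on the GC bin. For genes lower in dermis, higher in epidermis, 42 became 74 with pseudocount 0.1 and 86 centred on the median gene.

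Lists outside the middle 95% of random lists whose median changed sign or reached 0 were these. For basal keratinocyte genes, E16.5 skin, 0.14 became -0.29 centred on the median gene and -0.24 centred on the GC bin. For spinous layer genes, E16.5 skin, 0.10 became -0.33 centred on the median gene and -0.37 centred on the GC bin. For hair placode and epithelial follicle signalling genes, E16.5 skin, 0.17 became -0.26 centred on the median gene and -0.33 centred on the GC bin. For dermal condensate and papilla genes, E16.5 skin, 0.13 became -0.29 centred on the median gene and -0.24 centred on the GC bin. For dermal fibroblast matrix genes, E16.5 skin, 0.25 became -0.17 centred on the median gene and -0.16 centred on the GC bin. For immediate-early and heat shock genes, E16.5 skin, 0.21 became -0.22 centred on the median gene and -0.10 centred on the GC bin. For adipocyte genes, E18.5 epidermis, -0.89 became 0.28 at 5 FPKM. For Hox genes, E18.5 epidermis, 0.23 became 0 without a filter. Lists within the middle 95% of random lists that changed sign at E16.5, each below 0 centred on the median gene (given here) and on the GC bin, were retinoid synthesis, transport and receptors (0.30 to -0.13), periderm and simple or mucosal keratin genes (0.39 to -0.04), skeletal muscle genes (0.34 to -0.09), melanocyte genes (0.16 to -0.27), Schwann cell and nerve genes (0.33 to -0.10), endothelial genes (0.33 to -0.10), macrophage, mast cell and other immune genes (0.33 to -0.09) and Hox genes (0.34 to -0.09). At E18.5 they were retinoid synthesis, transport and receptors, E18.5 dermis (-0.54 to 0.08 without a filter), barrier lipid genes, E18.5 dermis (-0.36 to 0.00 at 5 FPKM), dermal condensate and papilla genes, E18.5 dermis (-0.03 to 0.14 without a filter), cartilage and bone genes, E18.5 dermis (-0.31 to 0.14 centred on the GC bin), erythroid genes, E18.5 epidermis (-0.02 to 0.15 centred on the median gene) and erythroid genes, E18.5 epidermis (-0.02 to 0.05 centred on the GC bin). The E16.5 lists with a positive median on the authors' scaling and a negative one after centring are those that rose less than the median gene. Among single lists and genes, 729 alternative values stayed within their error or on their side of the threshold and 133 moved by more or across 0, and 3 gained a call.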

Other observations

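The lists of antigen presentation, leukocyte, lens and retina genes used here were written after the data had been seen, and the comparisons were chosen then. The class II antigen presentation list was prompted by the low class II genes of the E18.5 epidermis, so its percentile there is not given. Its median there was -2.94 relative to the median gene over 8 measured members, and all 8 were at least 2-fold lower. Cd74, the invariant chain, went from 172 to 0.59 FPKM (-6.59), and H2-DMb1, which loads peptides, from 10.2 to 0.66 FPKM (-2.58). Other leukocyte genes were lower (median -0.93, percentile 0), with Tyrobp from 70.3 to 17 FPKM and Coro1a from 57 to 21.9 FPKM. The class II list had a median of -0.07 in the dermis (percentile 36.47) and 0.22 in E16.5 skin (percentile 97.75), where 0 rose and 0 fell of 8. In the dermis labelled mutant the other leukocyte genes were higher (median 1.51, percentile 99.99). In E16.5 skin 0 rose and 1 fell of 13. The E18.5 percentiles of the leukocyte list carry little weight, because the immune list fixed before had gone the same way in both tissues.

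The lens lists were seen in E16.5 skin. Of the crystallin genes 15 of 16 rose relative to the median and 0 fell, with a list median of 6.15, and of the other lens fibre genes 7 of 14 rose. Of the retina and pigment epithelium genes 10 of 15 rose and 0 fell. In the dermis the crystallin list had a median of -1.04 (percentile 1.19) and in the epidermis -0.25 (percentile 42.69), and the other lens fibre genes a median of 0.18 in the dermis (percentile 59.88). Relative to genes of like GC content, the dermis percentiles were 46.87 for crystallins and 99.72 for the other lens fibre genes.

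The 12 Lce1 genes of the late cornified envelope list were lower by similar amounts in the dermis, where the list had a median of -1.87 with a bootstrap SE of 0.04 over 12 members. That SE treats the copies as independent and is too small if they share reads. In the dermis Lce1a2 went from 75.1 to 19.2 FPKM, while in the epidermis it went from 6396 to 8372 FPKM.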
